A study of Homo sapiens with 12 samples.

How the data were processed

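The study measured messenger RNA in SKBR3 cells under 4 treatments with 3 libraries each. GSK126 (5 µM) or vehicle was given from day -6, cells were split on day -3 and seeded on day -1 at 350000 cells per 6 cm plate, and lapatinib (100 nM) or vehicle was given on day 0, 24 h before harvest, per the labels' protocols. Per the same labels, total RNA was extracted with an RNeasy Plus Mini kit, libraries were made with a Kapa mRNA HyperPrep kit, and 75 bp single-end reads were taken on a NextSeq500.

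Per the submitters' processing notes, reads were aligned with STAR to the human genome build hg19 and normalized with DESeq2, with no versions given. The counter, the annotation and any filter are not stated there. The deposited values are a signal per gene and library, made by the authors as read counts divided by a size factor for each library. In each column every value was a whole multiple of the smallest value above 0 (100% of values within 0.01 of a whole number, largest gap 2.2e-09), so the reads behind the deposited values could be recovered. Size factors recomputed from those reads with DESeq2 equalled the ones read from the steps. The table held 22256 features, 86 of them spike-in transcripts, which left 22170 genes named by symbol alone. No coordinates are given there, so none are printed. In 27 cases a symbol had been turned into a date by spreadsheet software, and these genes are not named here. Without a statement on strand or on reads that match several genes, members of multigene families (HLA genes, ribosomal proteins) and overlapping genes may share reads, and their single values are less certain.

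The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean for each group, all 12 libraries in the fit (8 residual degrees of freedom), a trended prior variance and Benjamini-Hochberg adjustment over the genes tested in a comparison, called at an adjusted p under 0.05. A gene was tested with a value of at least 10 in at least 3 libraries, which left 14179 genes. The 6 comparisons were each drug against DMSO, both drugs against each drug and against DMSO, and the interaction. Gene lists fixed before the data were examined (31 lists, 28 of them with at least 5 tested members) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. In each list that passed, the median, the mean and the test had the same sign. Members were also adjusted over the list alone. Beside tables of called genes, the number of genes under 5 in every DMSO library and called higher was counted.

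Genes named in the text were chosen by a rule set before the data were examined. For each comparison it takes, among genes past the threshold with a mean of at least 50 in the higher group and no overlap between the libraries, the 10 largest increases and the 10 largest decreases. It adds up to 4 members of each list with the smallest adjusted p, and in every comparison EZH2, ERBB2, ERBB3, EGFR, CCND1, MYC, DUSP6, CDKN1A and MKI67. The text gives a part of these. MALAT1, named for library quality, was chosen after its values were seen. For 3 libraries against 3, chance alone gives groups that do not overlap for 10% of genes.

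The procedure was tested on simulated data drawn from the real DMSO means and the real depths, with about 200 genes changed. Each gene had the same dispersion in all groups, noise was independent between genes, and only genes with a DMSO mean of at least 10 were changed. For lapatinib against DMSO (13195 genes) limma found 4.48% of the genes changed by 1.5-fold, 37.9% of those by 2-fold and 97.0% of those by 4-fold. For GSK126 against DMSO (13199 genes) the shares were 5.97%, 38.8% and 87.9%. For the interaction (13188 genes) 0% of the genes changed by 1.5-fold (0 of 67 at an adjusted p under 0.05), 17.9% of the genes changed by 2-fold and 66.7% of those by 4-fold were found. Wrong calls were 9 of 101, 4 of 92 and 4 of 60. The real groups differ in spread (median SD on the log2 scale 0.116 with lapatinib and 0.432 with GSK126). These shares therefore do not cover unequal spread, noise shared by genes, or genes near silent in DMSO.

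The alternatives set before the data were examined were pseudocounts of 0.5 and 5, no filter and a filter of 50, 3 other scalings (TMM, upper quartile and total count), a constant prior variance, a fit of only the groups compared, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, an estimated correlation or fry for the lists, ceilings of 2 and 10 for silent genes, and leaving out each library. Added after the data were seen were the spike-in composition as a term, leaving out the 3 libraries of the second composition, scaling to the spike-in total, and limma array weights. Transcript lengths, GC content and the order of genes came from a GENCODE annotation of another build than hg19, matched by symbol and used for no coordinate.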

Results

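The libraries measured messenger RNA from SKBR3, an established breast cancer cell line in which the HER2 gene (ERBB2) is amplified. Cells received vehicle (DMSO), 100 nM lapatinib, 5 µM GSK126 or both drugs, with 3 libraries in each of the 4 groups. Lapatinib inhibits the kinases of EGFR and HER2. GSK126 inhibits EZH2, the histone methyltransferase subunit of the repressive complex PRC2. GSK126 was present for 7 days and lapatinib for the last 24 h, per the labels' protocols. The 12 libraries held 18.0 to 30.5 M counted reads, with 18.0 M in the first combination library. The levels below are normalized read counts, given as mean ± SD (n = 3 libraries). Changes are log2 fold changes ± SE on the log2(value + 1) scale, so the change of a gene near 0 depends on the pseudocount. The p-values measure only the spread between libraries, because the labels do not say whether the 3 libraries of a group came from separate cultures. That spread is pooled over all 4 groups, although the groups differ in it (median SD 0.116 with lapatinib and 0.432 with GSK126). A fit of only the groups compared called fewer genes for GSK126 against DMSO and for both drugs against GSK126. It called more for lapatinib against DMSO and for both drugs against lapatinib.

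Libraries of a group correlated across genes at r from 0.990 to 0.991 with lapatinib, 0.974 to 0.983 with DMSO, 0.976 to 0.987 with both drugs and 0.936 to 0.976 with GSK126. The median SD of a gene between libraries, on the log2 scale, was 0.116, 0.243, 0.203 and 0.432 in the same order. Spike-in transcripts, an outside standard whose addition the labels do not describe, split the libraries by the proportions of the spike-ins among themselves. The first composition held 8 libraries (all DMSO, all lapatinib, and combination libraries 2 and 3), another held 3 (GSK126 libraries 2 and 3 and combination library 1), and GSK126 library 1 had its own. MALAT1, a nuclear RNA whose share can move with library quality, took 1.05% to 4.29% of the gene reads of a library, with 4.29% in combination library 3 and 4.04% in GSK126 library 1. It took 2.18% to 2.67% in the lapatinib libraries, 2.34% to 4.29% in the combination libraries and 1.29% to 2.09% in the DMSO libraries. This share was thus higher with lapatinib and with both drugs than with DMSO. Whether library quality or the expression of MALAT1 moved it was not tested. Combination library 1 had reads in 21669 genes, against 15059 to 17338 in the others.

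**Figure D1:**
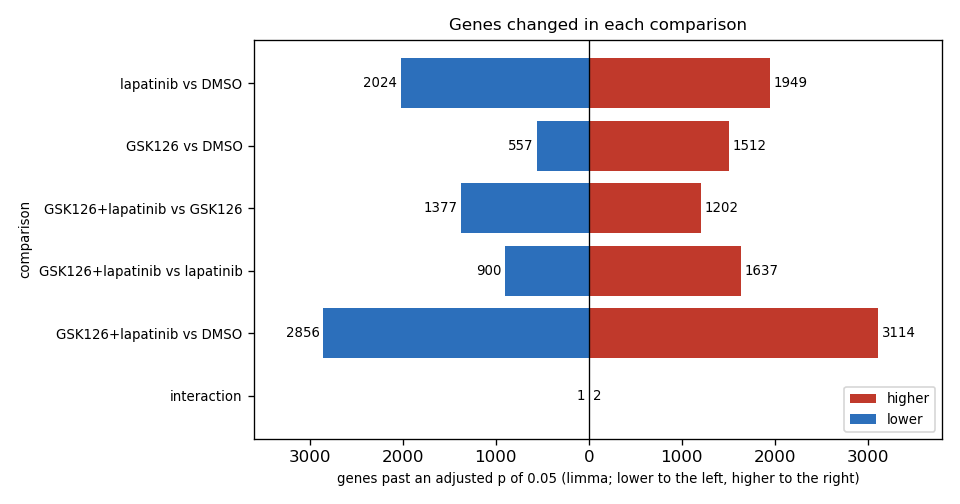
Genes past an adjusted p of 0.05 (limma) in each comparison, with genes lower in the first-named group as bars to the left and genes higher as bars to the right. Lapatinib against DMSO gave 1949 higher and 2024 lower genes, GSK126 against DMSO 1512 and 557, and the interaction 2 and 1.

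Lapatinib against DMSO asks what blocking HER2 signalling does to SKBR3 cells within a day. Genes of cell division fell together. RRM2, a subunit of the enzyme that makes deoxynucleotides, went from 9462 ± 863 to 632.3 ± 18.1 (n = 3), and the proliferation marker MKI67 from 8046 ± 482 to 1077 ± 38.9. The transcription factor MYBL2 fell by 3.93 ± 0.17 on the log2 scale (adjusted p = 6.55e-08). All 32 tested genes of DNA replication fell (32 adjusted over the list alone), among them CLSPN, GINS2, MCM10 and CDC45, and so did all 29 tested genes of mitosis (29 adjusted over the list alone), among them UBE2C and FOXM1. Ribosome biogenesis had 18 of 24 genes lower (20 adjusted over the list alone, adjusted p = 2.24e-07, and adjusted p = 0.0502 with an estimated correlation). EZH2 itself fell from 1549 ± 14.7 to 464.7 ± 28.1 (log2 change -1.74 ± 0.13, adjusted p = 1.84e-06). Of the 11 tested PRC2 subunits 4 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.0442, and adjusted p = 0.18 with an estimated correlation), EED and SUZ12 (adjusted p = 0.0622 without DMSO library 3) among those that fell.

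Output genes of the ERK pathway were lower for 9 of 19 (10 adjusted over the list alone, adjusted p = 6.97e-05, and adjusted p = 0.0811 with an estimated correlation). ETV4, a transcription factor downstream of ERK, went from 184.8 ± 25.1 to 16.67 ± 5.54, and CCND1, which encodes cyclin D1, fell by 1.47 ± 0.15. MYC (log2 change -0.17 ± 0.41, adjusted p = 0.782) and DUSP6 (-0.57 ± 0.37, adjusted p = 0.268) did not pass. Targets of the FOXO transcription factors, which act when AKT signalling is low, had 13 of 20 genes higher and 1 lower (13 and 3 adjusted over the list alone, adjusted p = 1.09e-05, and adjusted p = 0.0942 with an estimated correlation). FBXO32, a ubiquitin ligase gene, rose from 1106 ± 24.6 to 4829 ± 126. Milk and secretory mammary genes had 8 of 13 higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.00117), with PIP, ELF5 and MUC1 among the 8, and passed with an estimated correlation too (adjusted p = 0.0368). The luminal (adjusted p = 0.113), basal (0.599) and developmental (0.211) lists did not pass. ERBB2 rose from 154300 ± 11800 to 297600 ± 7690 (log2 change 0.95 ± 0.20, adjusted p = 0.00399), and ERBB3 by 0.83 ± 0.18. The receptor tyrosine kinase list had 5 of 15 genes higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0461, and adjusted p = 0.171 with an estimated correlation), while EGFR did not pass (0.29 ± 0.34, adjusted p = 0.549). The cell cycle inhibitor CDKN1A fell by 0.66 ± 0.21 (adjusted p = 0.0345, and 0.151 without lapatinib library 3).

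Cholesterol synthesis had 13 of 23 genes lower and 1 higher (15 and 1 adjusted over the list alone, adjusted p = 2.23e-05), with the sterol sensor gene INSIG1 and the enzyme gene FDPS among the 13, while fatty acid synthesis did not pass (adjusted p = 0.841). Glycolysis had 9 of 20 lower (12 lower and 1 higher adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.237 with an estimated correlation). Lysosome and autophagy genes had 9 of 29 higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.0063, and adjusted p = 0.18 with an estimated correlation). The ribosomal proteins were shifted down as a list (adjusted p = 1.86e-05) with 2 of 75 members lower (0 adjusted over the list alone), and that shift was lost with an estimated correlation (adjusted p = 0.609). Their share of the reads was 8.75% to 9.73% in the lapatinib libraries and 12.5%, 9.37% and 11.1% in DMSO libraries 1, 2 and 3. Their genes lay at a median percentile of 89.8 on the main axis of the differences between libraries of a group, and those of ribosome biogenesis at 78.1. In all, 1949 genes rose and 2024 fell, of 14179 tested, with 891 and 961 of them by at least 2-fold. Leaving out a lapatinib library gave 2545, 2641 or 2574 genes in place of 3973, with the fewest higher (1151) without library 1 and the fewest lower (1342) without library 3. A fit of only the groups compared gave 3019 higher and 3072 lower. Scaling to the spike-ins moved the median of all genes by -0.53, and the medians of the receptor and lysosome lists then fell to -0.08 and -0.24. Under that scaling 42 genes were called higher and 743 lower. The lists are therefore described relative to the other genes.

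GSK126 against DMSO asks which genes come on when EZH2 is inhibited. Genes of antigen presentation and the interferon response rose together. PSMB8, a subunit of the immunoproteasome, went from 146.4 ± 14 to 2239 ± 445 (log2 change 3.91 ± 0.19, adjusted p = 1.19e-07), and the peptide transporter TAP1 from 595.1 ± 8.38 to 4064 ± 719. Of the 15 tested genes of MHC class I presentation 13 rose (15 adjusted over the list alone, adjusted p = 3.18e-16), among them HLA-C and PSMB9. The interferon response had 21 of 35 genes higher and 1 lower (24 and 1 adjusted over the list alone, adjusted p = 6.14e-14), among them DTX3L, PARP9 and IFITM1, and its transcription factor IRF1 rose from 244.2 ± 19.7 to 1907 ± 332. MHC class II presentation had 3 of 7 higher (adjusted p = 0.0345, and adjusted p = 0.14 with an estimated correlation). The increases were largest for genes close to silent in DMSO. Such genes pass the filter only where other groups raise them, so this pattern follows in part from the filter and the log2 scale. APOL1, a gene of innate defence, rose from 1.067 ± 1.85 to 147.4 ± 20.8, and the ubiquitin ligase gene TRIM31 from 3.769 ± 2.13 to 373.4 ± 71.8.

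Developmental transcription factors had 15 of 30 tested genes higher and 1 lower (17 and 3 adjusted over the list alone, adjusted p = 4.41e-05), including SOX9, GATA2 and FOXD1. The data held 91 members of this list, and 30 passed the filter. A member silent in DMSO is tested only where other groups raise it, so counts out of 30 are not a share of the whole list. HOX genes did not pass in camera (2 of 8 tested higher, 3 adjusted over the list alone, adjusted p = 0.0633, and 0.168 with an estimated correlation). In fry they passed upward (adjusted p = 0.0012). The data held 34 members of the HOX list, so the same limit holds for counts out of 8. Cancer-testis genes did not pass (1 of 13 tested higher, camera, adjusted p = 0.881). Milk and secretory genes had 6 of 13 higher (adjusted p = 0.000227), including STAT5A and LCN2. Among the calls from camera lost with an estimated correlation were FOXO targets (8 of 20 higher, 9 adjusted over the list alone, adjusted p = 0.000958, and adjusted p = 0.167 with an estimated correlation) and receptor tyrosine kinases (5 higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.00691 and 0.08). So were targets of YAP and TEAD (5 of 14 higher, adjusted p = 0.00351 and 0.168), the BCL2 family (6 of 15 higher, adjusted p = 0.0124 and 0.25) and basal and mesenchymal genes (3 of 11 higher, adjusted p = 0.0124 and 0.08). Lysosome genes (8 higher and 1 lower, adjusted p = 0.00351 and 0.14) and cell cycle inhibitors (3 of 12 higher, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0255 and 0.25) were lost too. Single members of these lists passed, among them CD44, a surface protein of basal cells (3.69 ± 0.24), the cell cycle inhibitor CDKN2B (2.12 ± 0.23), CDKN1A (1.33 ± 0.21, adjusted p = 0.000853), EGFR (1.08 ± 0.34, adjusted p = 0.0485, and 0.197 without DMSO library 1) and the pro-apoptotic BMF (2.30 ± 0.22).

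With GSK126 557 genes fell, a count that was 233 without DMSO library 1, 259 without DMSO library 3, 261 with total-count rescaling and 1330 without GSK126 library 1. A fit of only the groups compared gave 66 lower and 803 higher, and the composition term of 3 levels 55 and 391. The lipid synthesis regulator THRSP (-2.81 ± 0.28, adjusted p = 2.29e-05) and the noncoding RNA H19 (-1.88 ± 0.21) were among them. Luminal and hormone receptor genes had 6 of 20 lower and 2 higher (adjusted p = 0.0274, and adjusted p = 0.175 with an estimated correlation), with XBP1 and TFAP2A among the 6. DNA replication was shifted down with 5 of 32 members lower (11 adjusted over the list alone, adjusted p = 2.66e-06), while mitosis did not pass (adjusted p = 0.592) and MKI67 changed by 0.19 ± 0.16 (adjusted p = 0.498). Small downward shifts also passed in camera for ribosome biogenesis (1 lower, adjusted p = 0.00483 and 0.175 with an estimated correlation), cholesterol synthesis (1 lower, adjusted p = 0.0454 and 0.14), ribosomal proteins (1 lower, adjusted p = 6.37e-05 and 0.609) and glycolysis (4 lower and 3 higher, 8 and 3 adjusted over the list alone, adjusted p = 0.0393 and 0.353). The shift of ribosome biogenesis and ribosomal proteins was not shared by the libraries. Their medians against DMSO were 0.23 and 0.24 in GSK126 library 1, -0.52 and -0.79 in library 2 and -0.33 and -0.33 in library 3. Neither EZH2 (-0.17 ± 0.13, adjusted p = 0.469) nor ERBB2 (-0.39 ± 0.20, adjusted p = 0.246, and 0.0435 without GSK126 library 1) passed.

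Of the 1512 genes that rose with GSK126, 223 (14.7%) were under 5 in every DMSO library. Lapatinib raised 78 such genes (4.0% of its increases, and 46, 50 and 45 without lapatinib libraries 1, 2 and 3) and both drugs together 322 (10.3%). Such a gene is tested only where it reaches 10 in 3 libraries of other groups, so the counts are not given as a share of all silent genes. The count with both drugs rests in part on combination library 1. That library had a read in 89.0% of genes with 1 to 3 reads in the other 11 libraries together, against at most 10.6% for another library. How many of the 322 genes such reads lifted was not counted. The GSK126 libraries lie outside the spike-in composition that holds all DMSO libraries, so the contrast has no library pair within a composition. With both drugs, combination libraries 2 and 3 share the composition of the lapatinib libraries. In that comparison, which uses none of the GSK126 or DMSO libraries, 1472 of the 1512 raised genes were higher and 540 of the 557 lowered genes were lower. The median change there was 2.86 for MHC class I genes and 2.65 for the interferon list. DNA replication (-0.021), ribosome biogenesis (0.033) and ribosomal proteins (0.007) had medians near 0 there, so their downward shifts with GSK126 were not seen in it. Cholesterol synthesis (-0.237), glycolysis (-0.245) and luminal genes (-0.352) had medians below 0. Both sides of that comparison had lapatinib. Lapatinib against DMSO lowered DNA replication by itself (median -2.04). The comparison therefore does not test the shift of that list with GSK126 alone. The medians of DNA replication against DMSO were -0.48, -0.31 and -0.41 in GSK126 libraries 1, 2 and 3. A fit with the composition as a term of 3 levels called 446 genes for GSK126 against DMSO in place of 2069, and leaving out GSK126 library 1 gave 3252. Markers of other cell types moved apart within their lists. Of the fibroblast markers, the collagen gene COL1A2 went from 37.86 ± 4.7 to 0 in each GSK126 library while ACTA2 rose by 1.25 ± 0.25 (adjusted p = 0.00393, and 0.0551 in a fit of only the groups compared), and the list as a whole did not pass (adjusted p = 0.592). Of the endothelial markers, the cadherin gene CDH5 rose by 3.14 ± 0.26 while VWF fell by 1.35 ± 0.39 (adjusted p = 0.0344, and 0.109 without DMSO library 1).

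**Figure D2:**
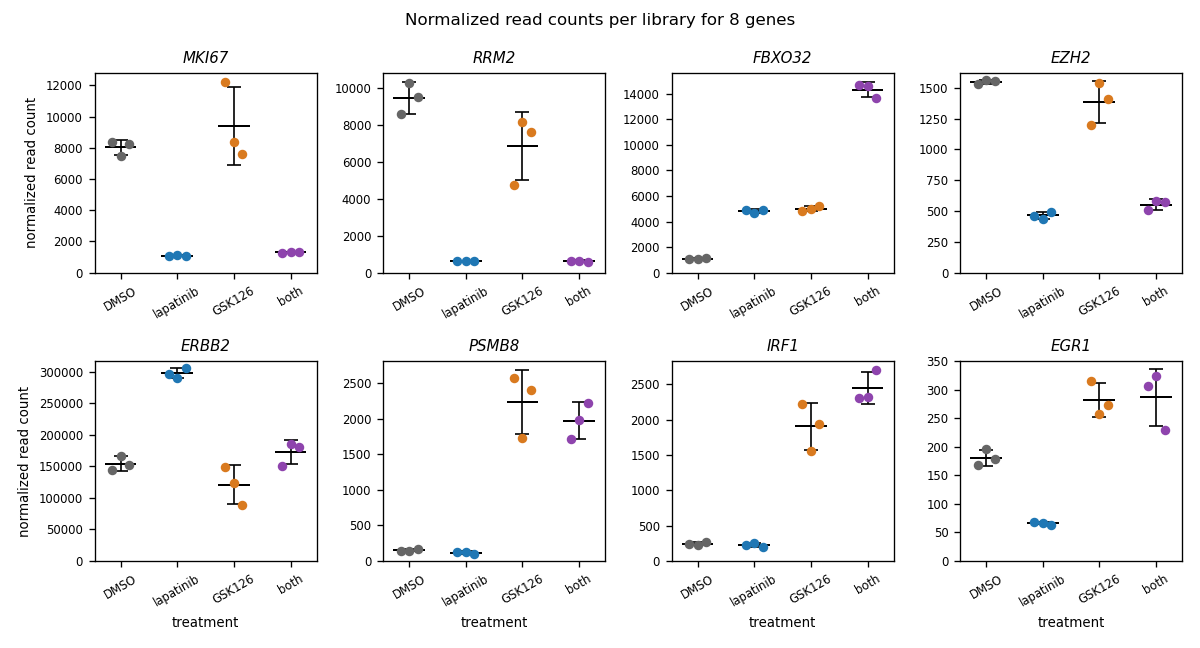
Normalized read counts of 8 genes, with treatment on the x axis, a point for each library, a line at the mean and bars for the SD (n = 3 libraries per treatment), on linear axes. MKI67 and RRM2 are low in both lapatinib groups, PSMB8 and IRF1 are high in both GSK126 groups, and FBXO32 is highest with both drugs (14330 ± 602).

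GSK126 with lapatinib against lapatinib alone asks how lapatinib-treated cells differ when EZH2 was already inhibited. PSMB8 went from 116.5 ± 17.3 to 1975 ± 257 and IRF1 from 224.3 ± 30.4 to 2447 ± 221. MHC class I presentation had 14 of 15 genes higher (15 adjusted over the list alone, adjusted p = 4.28e-16), and the interferon response 27 of 35 (29 higher and 1 lower adjusted over the list alone, adjusted p = 8.49e-16), OAS1 among them. ERK output genes were higher for 10 of 19 and lower for 1 (12 and 1 adjusted over the list alone, adjusted p = 4.29e-05, and adjusted p = 0.0706 with an estimated correlation). The immediate early gene EGR1 went from 66.14 ± 2.03 to 287 ± 49.9, and FOS rose by 3.39 ± 0.39. Targets of YAP and TEAD had 6 of 14 higher (adjusted p = 0.00254 and 0.16 with an estimated correlation), CTGF and NT5E among them. The ATF4 response, which cells use under amino acid or endoplasmic reticulum stress, had 7 of 18 higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 0.00442 and 0.192), with CHAC1 from 241.9 ± 11.1 to 1785 ± 36.8.

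Developmental factors (11 of 30 higher and 3 lower, 14 and 4 adjusted over the list alone, adjusted p = 0.00525 and 0.0697 with an estimated correlation), lysosome genes (7 of 29 higher, adjusted p = 0.00736 and 0.16), milk genes (5 higher and 1 lower, adjusted p = 0.0102 and 0.0706) and MHC class II presentation (4 higher and 1 lower, adjusted p = 0.0473 and 0.16) also passed in camera. Lower lists were the luminal genes (8 of 20 lower and 2 higher, 9 and 2 adjusted over the list alone, adjusted p = 0.00442 and 0.131), cholesterol synthesis (3 lower, adjusted p = 0.0148 and 0.0706), ribosomal proteins (adjusted p = 0.0243 and 0.703) and the HER2 amplicon (4 of 9 lower and 1 higher, 6 and 2 adjusted over the list alone, adjusted p = 0.0158 and 0.282). ERBB2 was lower with both drugs (172300 ± 18600) than with lapatinib alone, a log2 change of -0.79 ± 0.20 (adjusted p = 0.0141, and 0.0683 without combination library 1). FGFR4 (-2.28 ± 0.15), a receptor tyrosine kinase gene, was lower too, and CDKN1A was higher (1.65 ± 0.21). The largest increase among genes the naming rule covers was TRIM31 (7.74 ± 0.38, adjusted p = 5.46e-08), followed by the neuronal pentraxin receptor gene NPTXR (6.46 ± 0.60). EZH2 (0.25 ± 0.13, adjusted p = 0.254), mitosis (adjusted p = 0.0613) and DNA replication (adjusted p = 0.606) did not pass. In total 1637 genes rose and 900 fell. The lower count was 455, 467 and 538 without lapatinib libraries 1, 2 and 3, 565 and 503 without combination libraries 1 and 2, and 1562 without GSK126 library 1. A fit of only the groups compared gave 2668 higher and 2426 lower. Scaled to the spike-ins the median of all genes shifted by -0.46, and the medians of the lysosome, YAP and ATF4 lists fell to -0.34, -0.11 and -0.001.

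GSK126 with lapatinib against GSK126 alone asks what lapatinib does once EZH2 is inhibited. Cell division genes fell here as well. MYBL2 went from 11060 ± 2450 to 878 ± 69 and UBE2C, a mitotic ubiquitin enzyme, changed by -2.33 ± 0.11. All 29 mitosis genes (adjusted p = 7.71e-36) and all 32 DNA replication genes (adjusted p = 2.7e-35) were lower. Cholesterol synthesis had 13 of 23 lower (18 lower and 1 higher adjusted over the list alone, adjusted p = 9.08e-08). EZH2 fell by 1.32 ± 0.13 (adjusted p = 2.51e-05) and CCND1 by 0.73 ± 0.15 (adjusted p = 0.00504). ERBB3 rose by 0.62 ± 0.18 (adjusted p = 0.0307, and 0.0951 without combination library 3), a change that was -0.42 when scaled to the spike-ins, and ERBB2 did not pass (0.54 ± 0.20, adjusted p = 0.0793), though it did in 5 of the 24 alternatives set in advance (0.0152 without GSK126 library 1). The cell adhesion gene CEACAM5 rose by 3.38 ± 0.19 (adjusted p = 3.47e-07).

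Milk and secretory genes had 6 of 13 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.00151), and here the list also passed with an estimated correlation (adjusted p = 0.0408). Calls lost with an estimated correlation covered ribosome biogenesis (8 of 24 lower, 15 adjusted over the list alone, adjusted p = 8.62e-06 and 0.0985), FOXO targets (10 higher and 2 lower, 12 and 2 adjusted over the list alone, adjusted p = 0.000137 and 0.124), lysosome genes (8 higher and 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 0.000976 and 0.124) and ribosomal proteins (adjusted p = 0.000976 and 0.718). They covered also glycolysis (9 of 20 lower and 1 higher, 10 and 2 adjusted over the list alone, adjusted p = 0.00891 and 0.286), the interferon list (7 higher and 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 0.0175 and 0.124), HOX genes (4 of 8 lower, 5 adjusted over the list alone, adjusted p = 0.0194 and 0.115) and PRC2 subunits (4 of 11 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.0321 and 0.15). ERK output genes did not pass (1 higher and 2 lower, adjusted p = 0.439). In total 1202 genes rose and 1377 fell, and the sum of 2579 was 4411 without GSK126 library 2, 1494 without combination library 1 and 1361 without combination library 2. Without combination library 3, 769 rose, and in a fit of only the groups compared 355 rose and 593 fell. Scaled to the spike-ins the median of all genes shifted by -1.03, and the medians of the FOXO, interferon and lysosome lists fell to -0.36, -0.40 and -0.70. Of the 3057 genes then called, 13 were higher.

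Both drugs against DMSO gave the largest count, 3114 genes higher and 2856 lower (1812 lower with total-count rescaling). Scaled to the spike-ins, 598 of the 4709 genes called were higher. FBXO32 went from 1106 ± 24.6 to 14330 ± 602 and CHAC1, which degrades glutathione, from 64.88 ± 10.8 to 1785 ± 36.8. Secretory genes were among the increases, with PIP at 3.86 ± 0.22 and SCGB2A2, a secreted mammary protein, at 3.08 ± 0.14. All 32 DNA replication genes (adjusted p = 1.3e-24) and all 29 mitosis genes (adjusted p = 4.21e-22) fell, while 27 of 35 interferon genes rose and 1 fell (28 and 1 adjusted over the list alone, adjusted p = 5.81e-10) and 14 of 15 MHC class I genes rose (15 adjusted over the list alone, adjusted p = 1.06e-08). Cholesterol synthesis had 17 of 23 lower (adjusted p = 9.12e-07), ribosome biogenesis 17 of 24 lower (20 adjusted over the list alone, adjusted p = 9.01e-07), milk genes 9 of 13 higher and 1 lower (adjusted p = 7.25e-05) and developmental factors 14 of 30 higher and 3 lower (adjusted p = 0.00388). EZH2 fell by 1.49 ± 0.13 and CCND1 by 1.02 ± 0.15. ERBB2 did not pass (0.16 ± 0.20, adjusted p = 0.561). Increases of ERBB3 (0.84 ± 0.18, adjusted p = 0.0024) and CDKN1A (0.99 ± 0.21, adjusted p = 0.0024) became -0.17 and -0.01 when scaled to the spike-ins, a scaling under which the median of all genes shifted by -1.00.

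The lists whose calls were lost with an estimated correlation in this comparison were FOXO targets (14 of 20 higher and 2 lower, adjusted p = 1.26e-05 and 0.0758), lysosome genes (16 of 29 higher and 2 lower, adjusted p = 4.85e-05 and 0.0503), receptor tyrosine kinases (8 of 15 higher and 1 lower, adjusted p = 0.0174 and 0.0758) and cell cycle inhibitors (7 of 12 higher and 2 lower, adjusted p = 0.0453 and 0.38). Glycolysis (12 of 20 lower and 2 higher, 13 and 4 adjusted over the list alone, adjusted p = 0.00552 and 0.251), fatty acid synthesis (8 of 17 lower and 1 higher, 9 and 1 adjusted over the list alone, adjusted p = 0.0432 and 0.522) and ribosomal proteins (25 of 75 lower, adjusted p = 1.16e-07 and 0.522) were the lower ones. Scaled to the spike-ins, the medians of the receptor, cell cycle inhibitor, developmental and lysosome lists fell to -0.16, -0.14, -0.22 and -0.43.

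The interaction asks whether the lapatinib effect differed with and without GSK126. It passed for 3 genes (limma), with 836 at an unadjusted p under 0.05. GPX3, a secreted glutathione peroxidase, was at 544.8 ± 93.8 with DMSO, 495.3 ± 43 with lapatinib, 1222 ± 242 with GSK126 and 6744 ± 626 with both drugs (interaction 2.61 ± 0.24, adjusted p = 0.00138). The kinase gene DAPK2 was at 61.97 ± 11.8, 23.53 ± 2.54, 114.5 ± 17.9 and 228.2 ± 32.9 in that order (2.34 ± 0.33, adjusted p = 0.0466), and the amino acid transporter gene SLC16A10 at 207.3 ± 13.9, 256.9 ± 27.4, 92.37 ± 12.7 and 25.48 ± 5.45 (-2.13 ± 0.30, adjusted p = 0.0466). The calls of DAPK2 and SLC16A10 were lost in 14 and 15 of the 23 alternatives set in advance (adjusted p up to 0.254), and that of GPX3 in none of those. The count was 112 with DESeq2, 8 with a constant prior variance and between 1 and 18 when a library was left out. As lists, ERK output (8 higher adjusted over the list alone, adjusted p = 4.24e-10, and adjusted p = 0.0238 with an estimated correlation) and the ATF4 response (7 higher adjusted over the list alone, adjusted p = 2.07e-10 and 0.0294) shifted up with medians of 0.76 and 0.54. In EGR1 the lapatinib decrease seen without GSK126 was absent with it (282.6 ± 29.5 and 287 ± 49.9), and its interaction of 1.45 ± 0.26 (adjusted p = 0.102, and 0.0415 without GSK126 library 1) did not pass over all genes. DNA replication (adjusted p = 8.38e-09 and 0.0164, median 0.35) and mitosis (adjusted p = 0.00103 and 0.0251, median 0.23) shifted up too, so that relative to other genes the decrease with lapatinib was smaller in the presence of GSK126. Scaling to the spike-ins moved the interaction of all genes by a median of -0.50 and these medians with it, to -0.16 and -0.27. Relative to other genes DNA replication then still passed (adjusted p = 0.000853) and mitosis did not (0.0688). In the main fit GSK126 alone had already lowered DNA replication (median -0.41), and both drugs against lapatinib gave a median of -0.04 (camera, adjusted p = 0.606). Its smaller decrease thus went from a lower start to a like level. For mitosis these medians were -0.05 and 0.28 (camera, adjusted p = 0.592 and 0.0613).

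Lapatinib effects with and without GSK126 correlated at r = 0.757 across genes (Spearman rho = 0.758), with 857 genes higher in both comparisons against 165 for independent lists, 1138 lower in both against 197, and 2 and 4 in opposite directions. GSK126 effects with and without lapatinib correlated at r = 0.819 (rho = 0.677), with 1154 genes higher in both against 175, 325 lower in both against 35.4 and none in opposite directions. The genes are not independent replicates. The lapatinib and GSK126 effects, which share the DMSO libraries, correlated at r = 0.198. Groups simulated as unchanged, with the DMSO libraries drawn anew around their means as well, gave a mean r of 0.504 over 100 simulations. Their mean covariance was 0.0809 against the observed 0.153, a difference of 0.0716. Of the real calls for lapatinib and GSK126, 393 were higher in both (208 for independent lists), 175 lower in both (79.5), and 67 and 177 went in opposite directions. In none of the simulations was a gene called in both (limma), but no gene was changed in them. They therefore give no number for the overlap of unrelated responses. With the DMSO libraries split, so that a lone library served for a drug and the other 2 for the other (6 ways, chosen after the result was seen), r was 0.0429 to 0.103 and the covariance 0.0361 to 0.0928, with a mean of 0.0686. Genes higher in both then numbered 128 to 206 against 50.6 to 107 for independent lists, and genes lower in both 1 to 40 against 6.55 to 21.8. Genes lower with lapatinib and higher with GSK126 numbered 59 to 113, and genes higher with lapatinib and lower with GSK126 15 to 32. Numbers for independent lists were not computed for opposite directions. Among genes higher with GSK126, those also higher with lapatinib outnumbered those lower with lapatinib in each of the 6 splits. In the main fit lapatinib called about as many genes lower (2024) as higher (1949). Among genes lower with GSK126 neither direction of the lapatinib effect prevailed in all splits. Over all calls, an excess of the same direction over the opposite ones cannot be stated without those numbers.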

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

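The tests of GC content and length, of an unequal response over genes with a high adjusted p, of RNA from another cell type and of a few abundant genes, and the counts over regroupings and splits of the libraries, were set before their results were seen, and the other tests here were chosen after the result was seen. For the unequal response and for the spike-in composition a further version was added once the first value was known, and the values of both versions are given.

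The interaction singled out GPX3 (2.61), DAPK2 (2.34) and SLC16A10 (-2.13 on the log2 scale) as genes whose lapatinib effect differed with and without GSK126. The calls of DAPK2 and SLC16A10 were lost in 14 and 15 of the 23 alternatives set in advance, and that of GPX3 in none of those. In 2 of 100 regroupings of the residuals, the real one included, at least as many genes were called as the real 3, so regrouping by chance gave that count in a share of them under 0.05. The highest of the other regroupings called 1035 genes, which points to a structure of the samples beyond the treatments. This rests on that regrouping alone. Which structure it is, and whether the unequal spread of the groups gives it, was not tested. Among the lists, the interaction passed upward for ERK output (adjusted p = 4.24e-10), the ATF4 response (2.07e-10), DNA replication (8.38e-09), mitosis (0.00103) and ribosome biogenesis (0.0216), and downward for FOXO targets (0.00103) and luminal genes (0.0228). With an estimated correlation the first 4 of these passed and the other 3 did not (adjusted p = 0.358, 0.222 and 0.222). Scaled to the spike-ins, the interaction medians of DNA replication, mitosis and ribosome biogenesis fell below 0 (-0.16, -0.27 and -0.26) with the shift of all genes by -0.50, and relative to other genes DNA replication still passed there (adjusted p = 0.000853) while mitosis (0.0688) and ribosome biogenesis (0.337) did not.

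For the comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split was the only 1 of the 10 with so many genes at an adjusted p under 0.05. It called 3973 genes for lapatinib against DMSO, 2579 for both drugs against GSK126, 2537 for both against lapatinib and 5970 for both against DMSO, where the highest other split called 0 in each (limma, with all 12 libraries in the fit). At an unadjusted p under 0.05 the other splits reached up to 222, 4318, 120 and 981 genes, against 5639, 4646, 4054 and 7108 for the real split. For GSK126 against DMSO the real split called 2069 and the highest other 1441, with DMSO libraries 1 and 3 and GSK126 library 1 set against the rest. Those 3 libraries are also the ones of the 6 with the higher MALAT1 share of reads (2.02% or more, against 1.66% or less). At an unadjusted p under 0.05 another split of this comparison reached 4214 genes, more than the 3719 of the real split.

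The GSK126 libraries differed from each other more than those of the other groups, with a median SD of 0.432 on the log2 scale. Removing each library's trend on GC content and transcript length took it from 0.427 to 0.371 (93.1% of tested genes have a length), which argues against these trends as the whole cause. A library batch stays open, since the composition difference within the combination libraries correlated across genes with that within the GSK126 libraries (r = 0.334, Spearman rho = 0.510). This r does not single it out. Combination library 3 against the other 2, which uses the same libraries, gave r = -0.44. DMSO library 2 against the other DMSO libraries, all of the same composition, gave r = 0.366, and DMSO library 1 r = -0.308. Over the 11316 genes with a mean of at least 50 these values were 0.65, -0.725, 0.656 and -0.588. DMSO library 3 gave 0.0383 there and the lapatinib libraries -0.36 to 0.237. A quality axis through several groups thus stays open as well. GSK126 libraries 2 and 3 share a composition and still differed by a median of 0.401, against at most 0.353 for a pair in another group, which argues against the composition as the whole cause. An unequal response to GSK126 would leave other genes with a narrow spread, yet the median SD was 0.531 over 4649 genes with an adjusted p of at least 0.5 in both GSK126 comparisons, a choice that favours genes with a wide spread, and 0.393 over 4872 genes chosen without the GSK126 libraries, against 0.0961 to 0.208 in the other groups.

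Combination library 1 had reads in 2307 genes that had none in the other 11 libraries. Of 1641 genes with 1 to 3 reads in the other 11 together it had a read in 89.0%, against at most 10.6% when the same was asked of another library. In all 3948 genes with at most 3 reads elsewhere, a choice that holds the 2307 by construction, its reads made up 0.108% of its total. The library had 18.0 M reads against a median of 26.9 M in the others, which argues against depth as the cause. RNA of another cell type would concentrate in abundant transcripts, while the top 1% of these genes held 5.30% of the reads (5.62% within the 1641). An even background such as genomic DNA may be the source, as the reads rose with transcript length (Spearman rho = 0.386, and 0.466 within the 1641, with a mean of 7.22 reads in the longest of 4 length groups and 3.67 in the shortest). Apart from RNA of other cells, no biological explanation was tested.

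Spike-in transcripts, which the main comparisons do not use, took 1.01% of all reads. Their ratio to gene reads was higher with lapatinib than with DMSO by 0.709 on the log2 scale. With both drugs it was higher than with GSK126 by 1.19, a value that was 0.764 without GSK126 library 2. No GSK126 library shares the composition of combination libraries 2 and 3. Without the 10 most abundant genes of each library the first difference was 0.711, which argues against a few abundant genes, and all 6 of the DMSO and lapatinib libraries share a spike-in composition, which argues against that batch. Less polyadenylated RNA per cell with lapatinib may be the source, but the exact permutation test (2-sided) gave p = 0.1, the smallest that 3 libraries against 3 can give, and an unequal amount of added spike-in cannot be told apart from it.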

How the results depend on the processing

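The spike-in composition as a term, leaving out the 3 libraries of the second composition, scaling to the spike-in total and limma array weights were chosen after seeing the data, and the other alternatives were set before. Where no cause is named, the cause was not tested.

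Of 81 gene calls in the report, 71 were never lost under the alternatives set before, and of 77 list calls 27. Of 10 named gene results that did not pass, 3 passed in some: ERBB2 for both drugs against GSK126 (5 of 24) and for GSK126 (1), and EGR1 in the interaction (2 of 23, 0.000121 with DESeq2). Lost calls were those of EGFR (16 of 24 alternatives, adjusted p up to 0.197), VWF (10, up to 0.109) and ACTA2 (1, up to 0.0551) for GSK126 against DMSO, SLC16A10 (15 of 23, up to 0.254) and DAPK2 (14 of 23, up to 0.254) in the interaction, ERBB3 (9, up to 0.157) and CCND1 (1, up to 0.0725) for both drugs against GSK126, CDKN1A (8, up to 0.151) and SUZ12 (2, up to 0.0622) for lapatinib against DMSO, and ERBB2 (4, up to 0.107) for both drugs against lapatinib.

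The interaction count, 3 in the report, was 1 with no filter, 1 with total-count rescaling, 8 with a constant prior variance and 112 with DESeq2. A fit of only the groups compared, which takes the spread from those libraries alone, gave 6091 genes for lapatinib against DMSO, 869 for GSK126 against DMSO, 948 for both drugs against GSK126 and 5094 (2668 higher, 2426 lower) for both against lapatinib. With an estimated correlation 27 lists passed in place of 77.

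With the replicate block, the interaction gave 1 gene and lapatinib, GSK126, both against GSK126, both against lapatinib and both against DMSO gave 3731, 1809, 2299, 2295 and 5781. Replicate numbers did not pair the libraries, whose deviations correlated at r from -0.334 to 0.352, over 0.1 in 4 of 18 pairs, and 4 of 12 correlated best with their own number.

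The correlation of the lapatinib effects was 0.559 with no filter and 0.851 with a filter of 50, and that of the GSK126 effects 0.651 and 0.873. Silent genes raised by lapatinib, GSK126 and both drugs numbered 27, 101 and 141 with a ceiling of 2 and 136, 362 and 544 with a ceiling of 10, which admits more genes by construction.

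The composition term with 2 levels gave 4703 genes for both drugs against GSK126 and 1 for the interaction. With 3 levels the counts were 446 for GSK126 against DMSO, 1147 for both against GSK126 and 1 for the interaction, and 2068 of the 2069 genes kept their sign for GSK126 against DMSO. Leaving out the 3 libraries of the second composition keeps a lone GSK126 library, the first, assumed to vary like the other groups. The counts were then 6229, 4658 (2113 higher, 2545 lower) and 5897 for lapatinib, GSK126 and both against GSK126, and 593 for the interaction, with correlations of 0.599 for the lapatinib effects, 0.630 for the GSK126 effects and 0.042 between the drugs. Array weights gave, in the order used for the block, 7414, 4135, 7280, 8515, 9148 and for the interaction 3284.

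Scaling to the spike-in total gave 785 genes for lapatinib, 578 for GSK126, 3057 for both against GSK126, 408 for both against lapatinib and 4709 for both against DMSO. For the interaction limma called 0 (167 at an unadjusted p under 0.05, while edgeR and DESeq2 as deposited called 3 and 112). The share of higher calls went from 49.1% to 5.35% for lapatinib, from 73.1% to 97.8% for GSK126, from 46.6% to 0.425% for both against GSK126, from 64.5% to 80.1% for both against lapatinib and from 52.2% to 12.7% against DMSO. Under it the median of all genes shifted by -0.53, 0.04, -1.03, -0.46 and -1.00, and by -0.50 for the interaction. Total-count rescaling gave shares of 61.1%, 85.5%, 57.3%, 74.9% and 68.4% in the same order, with shifts of 0.16, 0.10, 0.15, 0.08 and 0.25, and upper-quartile rescaling 62.9% for both against DMSO (shift 0.14).

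Reversed under the spike-in scaling were CDKN1A (-0.011) and ERBB3 (-0.17) for both drugs against DMSO and ERBB3 (-0.42) for both against GSK126. The ribosomal protein list reversed with the 2-level term for GSK126 against DMSO (adjusted p = 0.389) and both against lapatinib (0.878), and without the 3 libraries for GSK126 against DMSO (0.103). Ribosome biogenesis reversed in the interaction without the 3 libraries (0.981).

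Leaving out a library gave 2545 to 5688 genes for lapatinib against DMSO, 1458 to 3252 for GSK126 against DMSO (3252 without GSK126 library 1), 1361 to 4411 for both against GSK126 (4411 without GSK126 library 2, 1494 and 1361 without combination libraries 1 and 2), 1739 to 3585 for both against lapatinib and 4577 to 7451 for both against DMSO. The interaction ranged from 1 to 18, with 18 without GSK126 library 1 and 1 without each DMSO or lapatinib library, GSK126 library 3 or combination libraries 2 or 3. Lists ranged from 71 to 82, the correlations from 0.699 to 0.756 (lapatinib effects, lowest without GSK126 library 2), 0.756 to 0.816 (GSK126 effects, the same) and 0.147 to 0.294 (between the drugs), and silent genes from 45 to 106 (46, 50 and 45 without lapatinib libraries 1, 2 and 3), 180 to 237 and 267 to 401.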

Other observations

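The first version of the EZH2 test and the share of neighbouring genes for GSK126 against DMSO were set before their results were seen, and the versions of the EZH2 test that follow the first were chosen after the result was seen, because the first shares the lapatinib libraries between the choice of genes and their effect.

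Lapatinib lowered EZH2 mRNA, so a hypothesis was that lapatinib alone may raise the genes that EZH2 inhibition raises. The 1281 genes at least 2-fold higher with both drugs than with lapatinib had a median lapatinib effect (without GSK126) of -0.144, below the random lists matched for expression (10000 lists, median 0.156), which went against the hypothesis by the bound set for it. The lapatinib libraries enter both sides with opposite signs there and push the value down. Genes chosen by GSK126 against DMSO (1177 genes), where the shared DMSO libraries push the value up, had a median of 0.249. With no library shared, over 3 splits of the DMSO libraries, the mean of the medians was 0.121, with 0.151, 0.066 and 0.145 against random medians of 0.188, 0.107 and 0.157. These lie at percentiles 10.5, 5.43 and 30.2 of the random lists, so this version leaves the hypothesis undecided and gives no value in its favour.

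A further hypothesis was that GSK126 may act on stretches of neighbouring genes. Of the genes raised at least 2-fold by GSK126 against DMSO, 10.8% had a next neighbour that was raised too, against a mean of 8.51% and a highest value of 11.8% in 1000 permutations of the gene order matched on mean level, 5 of which were as high as the real share. The bound set in advance asked for a share above every permutation, which was not met. The other comparisons were not set in advance. For both drugs against lapatinib the share was 14.1%, above every permutation (highest 11.9%), while genes raised by lapatinib gave 8.0% with 27 permutations as high, and by both drugs against GSK126 5.39% with 30 as high.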
